A study of Bifidobacterium bifidum PRL2010 and Bifidobacterium adolescentis
Bifidobacterium longum subsp. infantis ATCC 15697 = JCM 1222 = DSM 20088
Bifidobacterium bifidum PRL2010
Bifidobacterium breve 12L and Bifidobacterium adolescentis
Bifidobacterium bifidum PRL2010 with 5 samples.

How the data were processed

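Total RNA of 5 samples, each on 2 two-colour arrays, were analysed from the scanner files. Per the labels' protocols, 5 female mice per inoculation received 5 daily oral doses of 20 µl, 500 ng of total RNA was reverse transcribed and amplified, and 5 µg of cDNA was labelled with Cy5 or Cy3. The labels of the first sample name the strain once as B. breve PRL2010 and elsewhere as B. bifidum PRL2010, which is the name used here. They do not say whether the 2 arrays of a sample carry separate extracts, so these were taken as repeat measurements of 1 sample.

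The deposited array files hold each spot's intensity on a linear scale, the mean foreground and the median local background of both dyes, per the file headers. They also hold signals that Agilent Feature Extraction had already background-subtracted and dye-normalized (intensity as well). The deposited log10 ratio had been made by Agilent Feature Extraction from these processed signals, per the file headers, and was not used. The file headers give Feature Extraction 11.5.1.1, whereas the submitters' processing notes name Agilent Feature Extraction 10.10 and limma without a version. The authors' deposited value table holds 1 log2 ratio per PRL2010 gene and sample for 1646 genes. Its scale, centring and direction are unstated, and it was compared with the arrays for this reason: it followed the mean over a gene's probes of array II minus array I, divided by the number of arrays, with a correlation across genes of 0.96 to 0.98 and a slope of 0.93 to 0.99. Its column medians were 0.02 for the comparison with the food culture, -0.03 for all 4 species, -0.10 for 22L, -0.01 for 12L and -0.01 for ATCC15697. How its direction was chosen stays unknown. Its other upstream steps are not given in the sources used here.

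Each array file held 37603 spots. The PRL2010 set had 8130 probes of 1707 genes, the 22L set 7945 probes of 1664 genes, the 12L set 8697 probes of 1825 genes and the ATCC15697 set 11380 probes of 2400 genes, with 1 to 5 probes per PRL2010 gene. The 12L set was recognised by elimination from the prefix of its gene names. The reference table of gene names given for this work describes another strain of the species, matched 0 of the PRL2010 identifiers and was not used. For this reason the gene lists planned by product name could not be run.

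Foreground and background intensities were corrected with limma's normexp method with an offset of 50, control spots were left out afterwards, and spots marked as non-uniform or population outliers in either dye were removed. The log2 ratio of Cy5 over Cy3 was normalized within each array by loess (span 0.3, 4 iterations) fitted on the PRL2010 probes. The sign of array I was turned. A gene's value was the median over its probes, and a sample's value the mean of its 2 arrays. A gene entered when at least 50% of its probes were well above background, by Agilent's own mark, in Cy5 or in Cy3 on both arrays. In the comparisons of 1 sample, a gene was called when its log2 ratio was at least 1 in size with the same sign on both arrays. These settings, the tests and the alternatives were chosen before the data were examined, apart from the exceptions named here and in the closing section. So was a rule that a pair of arrays correlated below -0.3 has no settled direction. This applied to all 5 samples, for which the plan was to read Cy5 over Cy3 on both arrays and give counts with no direction. Turning array I and giving a likely direction beside the totals were chosen after the correlations were seen, on grounds stated with the results.

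Correlations between single channels and differences between dyes used log2 signals after normexp, quantile-normalized across all channels without loess. For the 4 samples with partners, limma's lmFit and eBayes tested the mean log2 ratio against 0 with Benjamini-Hochberg adjustment. Probe sequences of 60 bases were compared with blastn, and a probe matched another when at least 45 bases were identical: 1609 PRL2010 probes in 723 genes matched a probe of another strain. For the partner samples set against one another, a looser count was computed first and replaced by the planned rule after both had been seen. The planned rule for named genes takes the most extreme genes by mean log2 ratio among those called, limited to 2 in each direction because no names are paired with the identifiers. A gene that this rule names is not reported here. Agreement between probes of 1 gene was measured by the intraclass correlation, and the counts of called genes were set against 99 random groupings of the PRL2010 probes into genes of the same sizes. The steps were tested on simulated data in which 200 of 1707 genes changed and all probes of a gene changed together. In the 5 simulated comparisons of 1 sample, 90% to 97% of the genes changed by 1.5 on the log2 scale and 99% to 100% of those changed by 2.5 were recovered, with 0 calls among 1507 unchanged genes. In the simulated test over the 4 samples with partners, 100% were recovered at either size, with 8 calls among 1507 unchanged genes. Both simulated RNAs were equally bright apart from the changes, and every gene was measured, against 769 to 1399 genes in the 5 samples. Random groupings of the real probes gave medians of 8 to 35 called genes per comparison of 1 sample. The simulated rates therefore test the steps and do not carry over to these arrays.

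The alternatives were Agilent's processed signals centred on the PRL2010 median, loess on the probes of all 4 genomes, no loess, the mean over probes, no filter or a stricter one, matched probes left out, each array alone, the deposited value table and, for the partner samples together, each sample left out, the sample as a random block and scale normalization. Each sample's 2 arrays lay on a slide of their own, so slide and sample cannot be told apart and a separate slide block was not run. The analysis used R 4.3.3, limma 3.58.1, blastn 2.17.0 and matplotlib 3.10.9.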

Results

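RNA samples of Bifidobacterium bifidum PRL2010, a gut bacterium, alone or with partner strains, were compared on two-colour Agilent arrays that carried probes for 4 bifidobacterial genomes. Besides PRL2010, these were B. longum subsp. infantis ATCC15697, B. adolescentis 22L and B. breve 12L. Each of the 5 samples set 1 RNA against another on 2 arrays. In 1 sample, PRL2010 in mice that received it alone was set against PRL2010 grown in a mouse-food medium. In the other 4 samples, PRL2010 given to mice with partner strains (all 3 others, 22L, 12L or ATCC15697) was set against PRL2010 given alone. For 22L, 12L and ATCC15697, the protocols describe 5 mice for each strain and do not say whether the same mice received both, so "with" a partner means here that the label of the RNA names both strains. The series asks how bifidobacteria affect one another in the gut. Each group held 1 sample, so the comparisons of single samples have no replicate check and no p-value, and the SD given after each gene's log2 ratio is that between the 2 arrays of 1 sample. The number of arrays limits the precision. PRL2010 genes are given by the identifiers of the arrays, since the files pair them with no gene names, and at most 2 genes in each direction are named per comparison.

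The direction of the ratios was not settled by the labels, which give the same dyes for both arrays of a sample. Over all probes, the log2 ratios of array I and array II of 1 sample correlated at between -0.57 and -0.37, so 1 array of each pair must run the other way. Array I was turned, which makes the direction likely on 2 grounds. The deposited value table correlated across genes with array II as read at between 0.77 and 0.90 and with array I as read at between -0.87 and -0.85. The signals of 1 channel per array recurred on all 5 slides (r between 0.97 and 0.98 across PRL2010 probes with the dyes averaged). PRL2010 alone in mice is the one RNA that the labels give to every sample. The averaging hides that 2 profiles recur, 1 per dye, with r of 0.94 to 0.97 within a dye and 0.65 to 0.72 between the dyes. That both are of 1 RNA rests on the labels. The recurring channels correlated with those of the other RNAs at 0.41 to 0.65, which reaches the lowest value between their own dyes. Channels of the other RNAs correlated with one another across slides at 0.37 to 0.60. With the labels taken as right, these values argue against the opposite choice, under which the RNA common to all samples would not recur. With the opposite choice, every higher below reads as lower, and only the total counts are free of this choice. Genes and probes are not independent replicates in any of the correlations given here.

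The RNA that is likely PRL2010 alone in mice had the larger share of PRL2010 probes well above background on each of the 10 arrays, although on array II with 22L its median signal over background was lower, 563 against 709. Between 46.2% and 77.5% of the PRL2010 probes lay well above background in its channels, against 7.17% to 46.8% in the channels of the food culture and of the RNAs with partners, and these ranges trade places with the opposite choice of direction. The probes of strains 22L, 12L and ATCC15697 also lit up in that RNA. On the 2 arrays of the comparison with the food culture, where no partner strain was given, they were well above background in 64.4%, 62.9% and 67.5% of probes, compared with 75.4% of the PRL2010 probes and 0% of the 153 negative control spots. With the opposite choice, the shares on the 2 arrays are 5.02% and 14.02% for 22L, 4.70% and 13.5% for 12L, 6.48% and 17.0% for ATCC15697, and 7.17% and 21.0% for PRL2010. Within each dye, the channels of PRL2010 alone correlated across slides at 0.94 to 0.97, but between the dyes at only 0.65 to 0.72. The food culture correlated between the dyes at 0.67, the RNA with all 4 species at 0.77, and the RNAs with 22L, 12L and ATCC15697 at 0.90, 0.87 and 0.88.

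**Figure D1:**
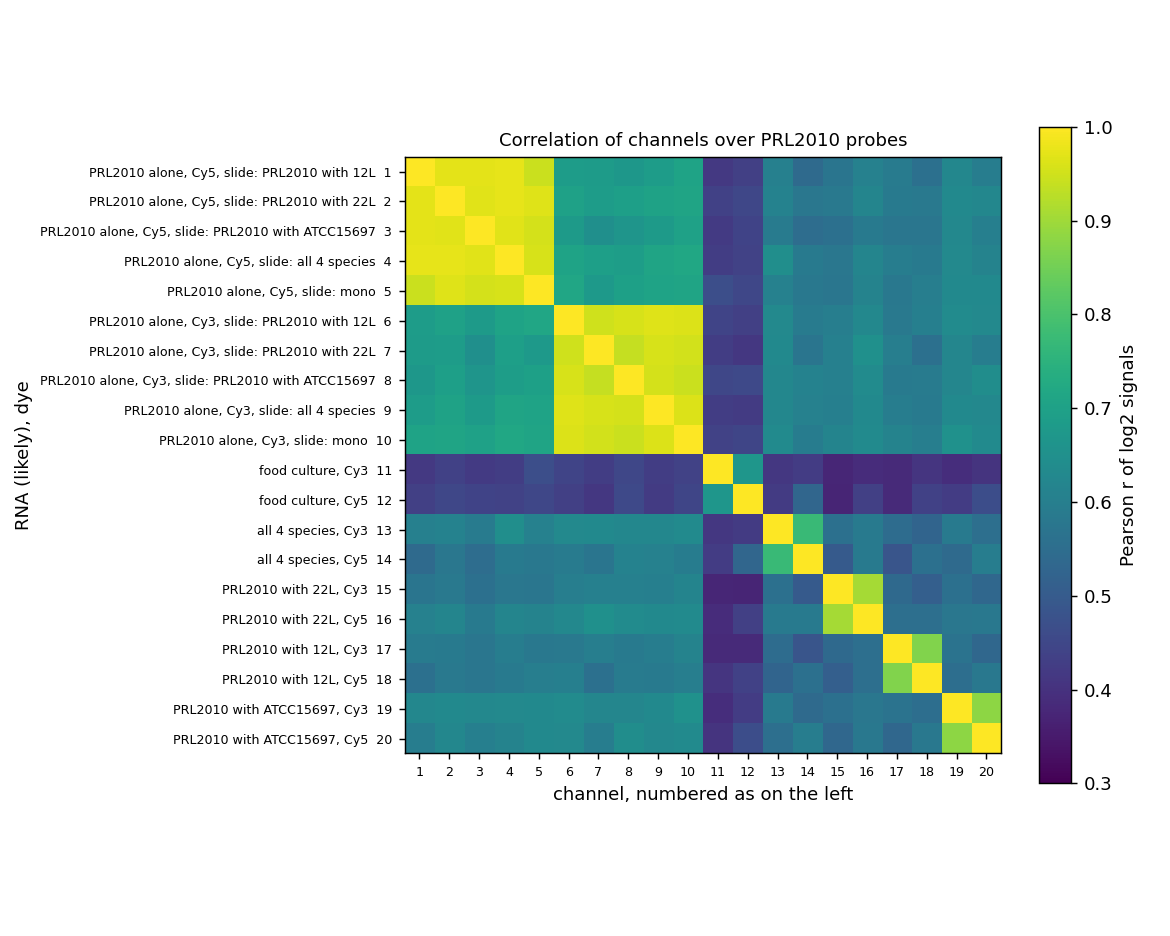
Pearson correlation of quantile-normalized log2 signals over PRL2010 probes between the 20 channels of the 10 arrays (colour scale), ordered by the likely RNA and the dye. The channels of PRL2010 alone form 1 block per dye, with r of 0.94 to 0.97 inside the blocks and 0.65 to 0.72 between them.

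Different probes of a PRL2010 gene did not give the same ratio. The intraclass correlation of the log2 ratios of probes of 1 gene lay between -0.02 and 0.02 in the 5 comparisons, inside the range of -0.02 to 0.02 found when the probes were assigned to genes at random. The signals of the RNA that is likely PRL2010 alone agreed more, at 0.0968 in Cy5 and 0.0703 in Cy3, against at most 0.0192 and 0.0168 at random. With GC content regressed out, these were 0.0224 and -0.0108. Ratios of probes of identical sequence, of which there were 356 sequences, correlated at 0.92 to 0.95. Between probes of different genes, the correlation was 0.05 to 0.12 with 25 to 34 identical bases of 60 and 0.51 to 0.63 with 55 to 59. The gene values and counts below are therefore medians over up to 5 probes that did not share a value. They may not measure the transcripts of the genes.

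**Figure D2:**
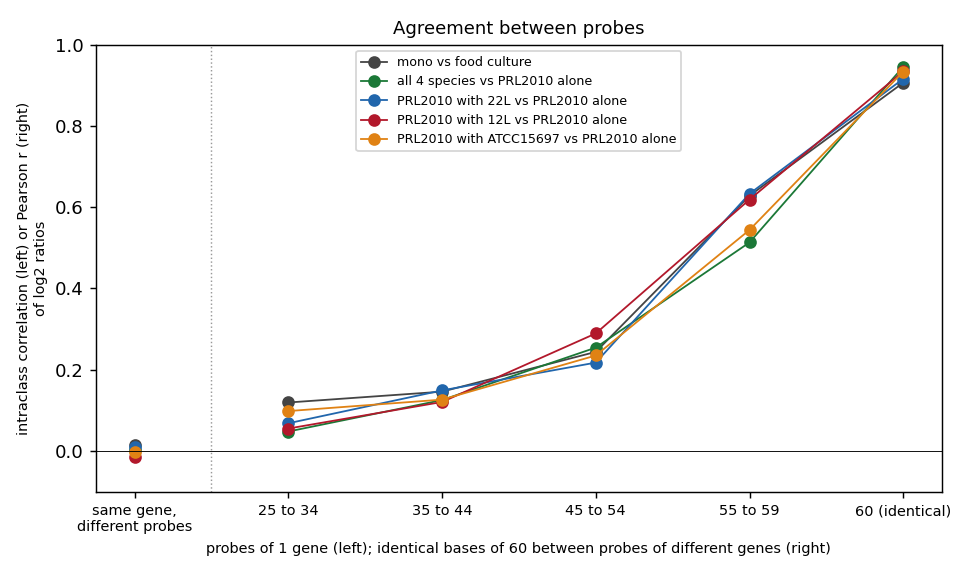
Agreement of log2 ratios for probes of 1 PRL2010 gene (left, intraclass correlation) and for probes of different genes by the number of identical bases of 60 (right, Pearson r), with 1 colour per comparison. Probes of 1 gene lie at about 0, while probes with 55 to 59 identical bases reach 0.51 to 0.63.

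In mice that received PRL2010 alone, 21 of 1389 measured PRL2010 genes passed the rule of at least a 2-fold difference from the food culture on both arrays. Of these, 2 were likely higher in mice and 19 likely lower. BBPR_1296 had the lowest log2 ratio, -3.63 ± 0.18 (SD, 2 arrays), and BBPR_0739 followed at -3.10 ± 1.53. Without loess they were at -1.99 and -1.74, and with Agilent's processed signals at -4.65 and -4.20. The 2 higher genes, BBPR_0359 and BBPR_1459, had log2 ratios of 1.21 and 1.20, but both were not well above background in the food culture, which leaves the size of these ratios open. With the mean over probes these were 0.82 and 0.96, and with Agilent's processed signals 2.24 and 0.67. For BBPR_1296, 3 of its 5 probes were at least 2-fold lower on both arrays and 4 matched a probe of another strain, and without those 4 its log2 ratio was -1.51. BBPR_0739 had 4 of 5 probes at least 2-fold lower. All probes of the gene had the sign of the call on both arrays in 3 of the 21 genes. In the comparisons below with all 4 species, 22L, 12L and ATCC15697, this held in 3 of 10, 7 of 29, 6 of 22 and 5 of 18. Genes with 3 or fewer probes were 7 of the 21, against 7.85% of measured genes. In the comparisons below they were 1 of 10, 5 of 29, 7 of 22 and 5 of 18, against 7.65% to 9.75% of measured genes. The split between the directions moved with the scaling, to 39 higher and 21 lower with Agilent's processed signals and to 137 higher and 21 lower without loess, and 12 and 6 of the 21 genes were among those called. Random groupings of the probes gave a median of 15 called genes.

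With all 4 species in the mice, 10 of 1399 measured PRL2010 genes differed at least 2-fold from PRL2010 alone on both arrays, 9 of them likely higher and 1 likely lower. BBPR_1271 was highest, with a log2 ratio of 2.58 ± 0.73 (SD, 2 arrays), which was 1.40 without loess and 3.44 with matched probes left out. BBPR_0715 was the single lower gene, at -1.89 ± 0.62. BBPR_1271 rests on 2 probes, of which 1 was at least 2-fold higher on both arrays. BBPR_0715 had 3 of 5 probes at least 2-fold lower on both arrays. Agilent's processed signals gave 22 higher and 31 lower genes, and the values without loess gave 10 higher and 63 lower, which held 10 and 1 of the 10 genes. Random groupings of the probes gave a median of 8 called genes.

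With B. adolescentis 22L as the partner, 29 of 1193 measured PRL2010 genes passed the rule, 19 likely higher and 10 likely lower than with PRL2010 alone. BBPR_0708 and BBPR_0147 were highest, at log2 ratios of 2.70 ± 0.78 and 2.64 ± 0.25 (SD, 2 arrays). BBPR_1475 and BBPR_1187 were lowest, at -1.65 ± 0.31 and -1.40 ± 0.04. With Agilent's processed signals they were at -2.09 and -0.94, the latter short of the limit of 1 in size. Without loess they were at -2.54 and -1.40. All 5 probes of BBPR_0147 were at least 2-fold higher on both arrays, although 4 of them match a probe of another strain, and the gene's log2 ratio without those was 2.30. One probe of BBPR_1475 had a mean log2 ratio of 1.39, against -2.70 for its lowest probe. The split moved to 28 higher and 45 lower with Agilent's processed signals and to 11 higher and 46 lower without loess, with 17 and 14 of the 29 genes among those called. Random groupings of the probes gave a median of 35 called genes, more than the 29 found.

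With B. breve 12L as the partner, 22 of 1207 measured PRL2010 genes passed the rule, 20 likely higher and 2 likely lower. BBPR_1323 had a log2 ratio of 3.89 ± 0.97 (SD, 2 arrays) and BBPR_0147 one of 3.06 ± 0.46. The 2 lower genes were BBPR_0715, at -1.69 ± 0.60, and BBPR_1335, at -1.45 ± 0.52. Both probes of BBPR_1323 were at least 2-fold higher on both arrays. Of the 5 probes of BBPR_0147, 4 were, and the probe means ran from -0.80 to 5.96. Without its 4 probes that match another strain, its log2 ratio was 4.50. Agilent's processed signals gave 36 higher and 43 lower genes, and the values without loess 7 higher and 75 lower, which held 20 and 9 of the 22 genes. The median of the random groupings was 22, equal to the count found.

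With B. longum subsp. infantis ATCC15697 as the partner, fewer PRL2010 genes could be measured, 769, and 18 of them passed the rule, 16 likely higher and 2 likely lower. BBPR_0898 and BBPR_1669 were highest, at 1.78 ± 0.34 and 1.76 ± 0.53 (SD, 2 arrays). The lower genes were BBPR_1520 and BBPR_1221, at -1.20 ± 0.08 and -1.19 ± 0.21. Both fell short of 1 in size with the mean over probes (-0.72 and -0.86) and in the deposited value table (-0.80 and -0.99). They were at -1.68 and -1.40 with Agilent's processed signals. Both probes of BBPR_0898 were at least 2-fold higher on both arrays, while BBPR_1520 and BBPR_1221 each had a probe with a mean log2 ratio above 1. Agilent's processed signals gave 12 higher and 36 lower genes, and the values without loess 2 higher and 31 lower, which held 10 and 4 of the 18 genes. The median of the random groupings was 18, again equal to the count found.

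**Figure D3:**
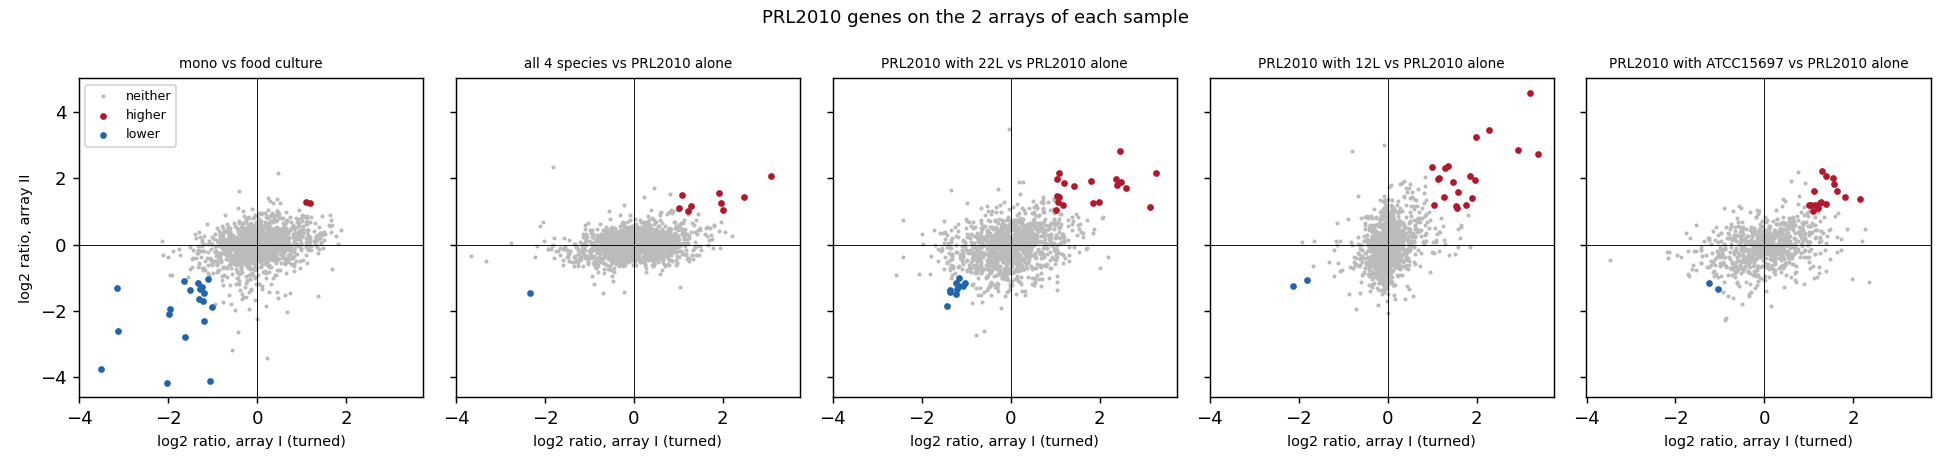
Log2 ratio of each measured PRL2010 gene on array I (turned, horizontal axis) and array II (vertical axis) of the 5 samples, with genes at least 2-fold higher or lower on both arrays in red and blue. Across genes the 2 arrays correlated at 0.24 to 0.40 (all PRL2010 genes), and between 10 and 29 genes per sample lie past the limits on both.

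Across the 4 samples with partners, limma found 14 of 739 PRL2010 genes shifted from PRL2010 alone at an adjusted p under 0.05, 2 likely higher and 12 likely lower, all with the same sign in 4 of 4 samples. BBPR_0147 was higher by 1.84 (SE 0.35, limma adjusted p = 0.0245) and BBPR_0898 by 1.36 (SE 0.19, limma adjusted p = 0.00870) on the log2 scale. BBPR_0715 and BBPR_1327 had the lowest ratios, -1.43 (SE 0.20, limma adjusted p = 0.00870) and -1.30 (SE 0.23, limma adjusted p = 0.0245). Array I of each sample alone gave -2.26 for BBPR_0715 and -2.43 for BBPR_1327, against -0.60 and -0.17 on array II alone, where neither passed. Neither passed with the mean over probes or in the deposited value table, BBPR_0715 did not pass with scale normalization, and BBPR_1327 did not pass with the sample as a random block or with matched probes left out. BBPR_0147 did not pass with array II alone (1.48), the mean over probes, no filter, scale normalization or the deposited value table, and was at 3.02 with matched probes left out. BBPR_0898 did not pass without loess (0.46) or in the deposited value table. The stricter filter, which needed both dyes well above background, left 32 genes to test. Of the genes named here it kept BBPR_0898, which passed, and left out BBPR_0147, BBPR_0715 and BBPR_1327. At an unadjusted p under 0.05, 138 genes passed. The 4 samples are different conditions set against 1 control, so the test leaves out the control's own spread and nothing in the labels says that the RNAs are of separate cultures. By limma, no gene passed without the sample with all 4 species (111 at an unadjusted p under 0.05) or without that with ATCC15697 (108), 2 passed without 22L, and 14 without 12L, of which 9 were among the first 14. The values without loess gave 3 higher and 225 lower genes, and 8 of 100 groupings of the probes, the real one included, gave 14 or more.

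**Figure D4:**
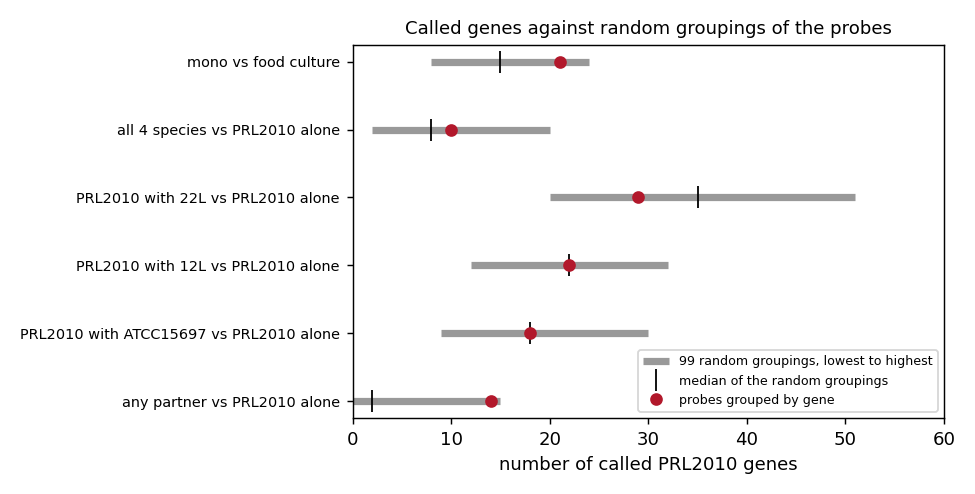
Number of called PRL2010 genes per comparison (horizontal axis) with the probes grouped by gene (red points) and in 99 random groupings (grey bars from lowest to highest, black line at the median). Each red point lies within its grey bar.

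The median log2 ratio of the partner strain's probe set lay close to that of the PRL2010 set in the sample with that partner. In the sample with 22L, the median log2 ratio of the 22L genes minus that of the PRL2010 genes was 0.00 ± 0.05 (SD, 2 arrays). The corresponding differences were 0.01 ± 0.00 for the 12L genes with 12L and 0.00 ± 0.02 for the ATCC15697 genes with ATCC15697. Of the 22L genes measured with 22L, 2.17% were likely higher by at least 2-fold on both arrays, against 1.59% of the PRL2010 genes and, for strains not given in this sample, 2.02% of the 12L and 1.94% of the ATCC15697 genes. The likely lower shares were 1.81%, 0.838%, 0.594% and 1.15%. Of the 12L genes measured with 12L, 2.74% were likely higher, against 1.66% of the PRL2010, 2.23% of the 22L and 1.64% of the ATCC15697 genes. The likely lower shares were 0.228%, 0.166%, 0% and 0.357%. Of the ATCC15697 genes measured with ATCC15697, 2.01% were likely higher, against 2.08% of the PRL2010, 1.46% of the 22L and 1.84% of the 12L genes. The likely lower shares were 0.709%, 0.260%, 0.624% and 0.408%. With the opposite choice of direction, these shares trade places. With all 4 species, the medians of the 4 probe sets lay between -0.02 and -0.01.

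Set against one another, the partner samples differed in 25 to 49 PRL2010 genes per pair, by at least 2-fold on both arrays and with every array of 1 sample above every array of the other. Between the samples with 22L and 12L, these were 49 of 1115 genes measured in both, and between those with 22L and ATCC15697, 40 of 746. The counts per pair were not set against random groupings of the probes, so chance is not excluded for them. The log2 ratios of 2 partner samples correlated across genes at 0.21 to 0.31, with a covariance of 0.05 to 0.08. A simulation gave 0.22 to 0.27 and 0.05 to 0.07. In it, the shared control and each sample's own change varied by the same amount, which was taken from these data. This equal split was assumed, so the likeness cannot tell how much of the correlation the control accounts for. Arrays of 2 partner samples with the control in the same dye correlated at 0.25 to 0.44, and arrays with the control in different dyes at -0.02 to 0.08.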

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

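The tests on identical probes, on similar sequences and on GC content were chosen after the result was seen; those on probe names and on random groupings were written before. Probes of strains that were not given lit up in the RNA taken as PRL2010 alone, where 64.43% of 22L, 62.89% of 12L and 67.5% of ATCC15697 probes were well above background, against 0% of negative control spots. With the opposite choice of direction, the shares on the 2 arrays are 5.02% and 14.02%, 4.70% and 13.5%, and 6.48% and 17.0%.

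Probes of 1 PRL2010 gene shared no more of their log2 ratio than probes assigned at random, and the counts of called genes were reached by random groupings in 9 of 100 (comparison with the food culture, 21 real, highest other 24), 32 (all 4 species, 10 and 20), 86 (22L, 29 and 51), 55 (12L, 22 and 32), 58 (ATCC15697, 18 and 30) and 8 (any partner, 14 and 15), the real grouping included, so chance is not excluded for any of these counts. These counts are over unlike numbers of measured genes. Random groupings measured more than the real one for the food culture (1423 to 1492 against 1389) and all 4 species (1402 to 1458 against 1399). The same held for 12L (1211 to 1278 against 1207), while the other ranges held the real number. Imprecise spots are argued against by identical probes, which correlated at 0.917 or more. Wrong gene names are argued against for genes with 2 or more matched probes, 211 to 253 of the 1707 PRL2010 genes per strain. Counted once per strain, 705 of 714 (98.7%) had matches that all pointed to 1 gene of the other strain. Names of the other genes were not checked. GC content is argued against as the cause, since the agreement of the ratios within genes was at most 0.013 with GC content regressed out; the signals of 1 RNA did agree within genes, at 0.0968 in Cy5 and 0.0703 in Cy3 and, with GC content regressed out, at 0.0224 and -0.0108. What stays open is that the ratios mainly follow each probe's own sequence, as the correlation of at least 0.513 between probes of different genes with 55 to 59 identical bases would need; RNA other than the gene's transcript or uneven amplification could give such a pattern, and neither was tested. No biological explanation was tested.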

How the results depend on the processing

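The alternatives were planned, except the test of each array number over the partner samples, chosen after seeing the data. Of 144 alternative values of the counts, probe sets and partner pairs, 44 stayed within the limits set for them and 100 did not. The causes were not tested, except where fewer genes or arrays enter by construction. Of 250 alternative values of single genes, 178 stayed within the limits set, 46 moved past the SD between arrays and 0 reversed. The other 26 lost the adjusted p under 0.05. Only the genes named over the partner samples carry an adjusted p, so these 26 belong to fewer values than 250. Genes called in 1 sample could neither reverse nor move past the SD on an array alone, since each array lies within the SD of their mean. These genes repeat their value under another filter, also where that filter leaves the gene out. Such values are among the 178 by construction and do not test the genes. No paired analysis was possible because each group has 1 sample and the labels share no replicate numbers beyond 1. The gene lists and the slide block were not run. The sample with ATCC15697 had the fewest genes measured, 769. On its array II, the channel taken as PRL2010 alone had 46.2% of PRL2010 probes well above background. The other channels of that RNA had 64.7% to 77.5%.

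Counts are given as higher and lower, in the order food culture, all 4 species, 22L, 12L, ATCC15697 and any partner. The counts were 2 and 19, 9 and 1, 19 and 10, 20 and 2, 16 and 2, and 2 and 12. With Agilent's processed signals they were 39 and 21, 22 and 31, 28 and 45, 36 and 43, 12 and 36, and 2 and 22. Without loess they were 137 and 21, 10 and 63, 11 and 46, 7 and 75, 2 and 31, and 3 and 225. These 2 settings moved the median log2 ratio of measured genes, to 0.14 and 0.24 for the food culture, -0.12 and -0.22 for all 4 species, -0.20 and -0.24 for 22L, -0.15 and -0.30 for 12L, and -0.23 and -0.27 for ATCC15697. With the mean over probes they were 0 and 50, 36 and 1, 43 and 8, 59 and 3, 32 and 6, and 1 and 1. With matched probes left out they were 11 and 38, 22 and 9, 37 and 16, 47 and 6, 34 and 18, and 2 and 6. With the stricter filter they were 0 and 7, 9 and 0, 15 and 1, 16 and 0, 13 and 0, and 3 and 0. This filter asked for at least 50% of a gene's probes well above background in both dyes on both arrays. In the comparisons of 1 sample, a call lost under it therefore had 1 RNA short of that mark on at least 1 array. Over the partner samples it left 32 genes to test, against 739. By the deposited value table, with the limit on the mean of the arrays, they were 25 and 52, 48 and 26, 49 and 56, 73 and 19, 50 and 25, and 0 and 1. Array I alone gave 92 and 81, 92 and 97, 87 and 92, 43 and 15, and 70 and 55, and over the partner samples 13 and 28. Array II alone gave 16 and 68, 19 and 6, 55 and 73, 77 and 63, and 33 and 32, and over the partner samples 2 and 8. With loess on all 4 genomes, 4 genes were lower with ATCC15697. Over the partner samples, no filter gave 1 and 11, the random block 3 and 7, and scale normalization 1 and 4. With each of the 4 partner samples left out in turn, the counts ran from 0 to 5 higher and from 0 to 9 lower. Of the genes called over the partner samples, 13 remained with Agilent's processed signals and 2 with the mean over probes.

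The difference between a partner's probe set and PRL2010's was 0.0576 for 22L and 0.113 for 12L with Agilent's processed signals. With matched probes left out it was 0.0331 for 12L and 0.0259 for ATCC15697. Agilent's processed signals gave 76, 109 and 61 genes apart between all 4 species and 22L, 12L and ATCC15697. They gave 100 between 22L and 12L, 73 between 22L and ATCC15697, and 78 between 12L and ATCC15697.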

Other observations

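The tests on the shared control, on the dyes and on neighbouring genes were chosen after the patterns were seen. PRL2010 genes whose probes all match probes of other strains did not stand apart from the rest. In the comparison with the food culture, 45 such genes had a median log2 ratio of -0.07, at percentile 12.5 of random lists matched on signal. With all 4 species, 44 such genes had a median of 0.02, at percentile 71.6. With 22L, 12L and ATCC15697, the percentiles were 70.9, 24.5 and 73.5 for 33, 35 and 18 genes. Of the 100 calls over the 5 comparisons of 1 sample, 83 lay on the side where the food culture or the RNA with partners had the higher normalized signal, compared with 119 of 313 with Agilent's processed signals, 51 of 403 without loess and 220 of 238 with the mean over probes. With the opposite choice of direction, these are 17, 194, 352 and 18.

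Consecutively numbered PRL2010 genes, many of which lie in 1 transcription unit in bacteria, were tested for shared log2 ratios, with numbers taken as the order of the genes. Their correlation lay between -0.09 and -0.01, and in no comparison above percentile 41.1 of 10000 random pairings, so these gene values show no shared change of neighbours.

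The RNA taken as PRL2010 alone gave different profiles in Cy5 and in Cy3, with an SD of the difference of 1.18 to 1.27 on the log2 scale, against 1.29 for the food culture and 0.67 to 1.05 for the RNAs with partners. Chance differences between arrays are argued against, since the difference repeated between slides with a correlation of at least 0.801. A dye effect of the probes shared by all RNAs is argued against, since the difference correlated with that of the food culture or partner RNA at -0.126 to -0.0357. The limit of this test, under 0.1 in size, was restated as under 0.1 with negative values included after -0.126 had been seen; by the first wording the test decided nothing. What stays open is that the Cy5 and Cy3 labelled material may come from separate preparations or animals, which no label records and which was not tested. No biological explanation was tested.

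The 14 PRL2010 genes shifted over the partner samples may owe their shift to the control that all 4 share. In the comparison with the food culture, where the same control RNA stands on the other side of the ratio, 12 of the 14 genes had the opposite sign, compared with 62.7% of all 739 genes (exact binomial test against that share, one-sided, p = 0.0599). The test was first made against an even split of the signs, by which the shared control was taken to explain the shift. It was remade against the share among all genes after the 12 of 14 had been seen, which changed the verdict to undecided. The shared control stays open and undecided, since the 14 genes were also chosen through ratios to it. BBPR_0147 and BBPR_1621 were the exceptions, the latter named after its value was seen. A response of PRL2010 to any partner that opposes its response to the mouse gut stays open for the 14 genes and was not tested. Across all genes, arrays of different partner samples correlated at 0.25 to 0.44 with the control in the same dye. With the control in different dyes, they correlated at -0.02 to 0.08. A response shared by all partners would need likeness in both cases. Across all genes, these values therefore argue against it as the main source of the likeness between partner samples. The 14 genes were not taken alone. Array I of each sample alone gave 41 called genes and array II alone 10, of which 11 and 4 were among the 14.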
